A study of Rattus norvegicus with 6 samples.

How the data were processed

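Kidney total RNA of 6 male rats was measured on a 1-colour small RNA array. Per the labels' protocols, about 1 µg of total RNA per rat was given a poly(A) tail and labelled with biotin using the FlashTag HSR kit, and each rat has 1 array. The hyperoxaluric group (n = 3) drank water to which ethylene glycol (1% by volume) and ammonium chloride (0.5%) had been added, and the control group (n = 3) drank tap water, both over 2 weeks. Per the series' design text, the 3 treated rats were those with the highest oxalate in 24-hour urine among the treated animals, so the spread among them is that of selected animals. Urinary oxalate was not analysed here.

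The deposited values are log2 intensities made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. Versions and probe annotation are not given in the sources used here. RMA corrects the background, makes the arrays' distributions alike and summarises the probes of a probe set. It fixes the overall level of every array, so a change of all small RNAs at once cannot be seen. Scanner intensities and detection calls were not analysed here. The log base was taken from RMA, which works in log2, and was not checked against scanner values.

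The table holds 36249 probe sets. By the form of their IDs, 30424 carry a mature miRBase accession, 3770 a miRBase stem-loop accession, 1491 an Ensembl gene number of the human series, and 505 the name of a small RNA, mostly a small nucleolar RNA (snoRNA). The remaining 59 are spike-in and hybridization controls, which were left out of every test. No table used here pairs the miRBase accessions with miRNA names or with a species. The miRNAs are therefore unnamed, rat probe sets could not be separated from those of other organisms, and at most 2 accessions per direction are printed. The reference gene table holds no miRBase accession, so it named 0 of these probe sets.

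Many probe sets carry exactly the same 6 values to the last digit, as they would if they shared their probes. Such probe sets were treated as 1 distinct signal, and counts are given both per probe set and per distinct signal. The table holds 25112 distinct signals, and 14174 probe sets share their values with at least 1 other probe set.

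Before the data were examined, the design named rat mature miRNAs as the features to test, and all probe sets above the median level where names could not be had. The second case applied. Control probe sets aside, 18075 probe sets (11030 distinct signals) had a mean over the 6 arrays above the median of all probe sets, 0.473 on the log2 scale. They were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, hyperoxaluric against control, no covariate). The limma p-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 18075 probe sets, with a threshold of 0.05. Differences are hyperoxaluric minus control. The fold screen stated by the series (above 2-fold or below 0.5-fold) was applied to the same probe sets, without a test. The planned tests of miRNA lists, of the 5p and 3p arms, of rat stem-loops and of orthologous probe sets need names and were not run. In place of rat stem-loops, all stem-loop probe sets were fitted apart. Shifts of probe set types and snoRNA families were tested with camera at a preset correlation of 0.01, a choice made after the data were seen, over distinct signals above log2 1 and for groups of at least 3.

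The printed accessions are the 2 signals per direction with the largest difference among those with adjusted p under 0.05 and no overlap between groups, as the rule set beforehand orders them, with the number lowered to 2. Where several IDs share a signal, the first ID stands for all. The named small RNAs with a mean above log2 4 were chosen after their values were seen. The titles number the rats 1 to 3 in both groups, with nothing to say that equal numbers share a litter or day. They also call every hyperoxaluric rat biological replicate 1 and every control rat biological replicate 2, which follows the groups and cannot be told apart from them; the rats were counted as n = 3 from the other numbers. The deviations from the group means of equally numbered arrays correlated at -0.155, -0.144 and -0.0756 for numbers 1, 2 and 3, across genes, so the numbers were not used to pair the rats.

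The precision is limited by the 3 arrays per group. The median SD within groups was 0.275 on the log2 scale for distinct signals above log2 8, 0.455 between log2 4 and 8, and 0.471 between log2 1 and 4. The fit was tested on simulated data with the levels and spreads of the 11030 distinct signals, drawn independently and adjusted over those signals. Of 50 simulated changes each, all planted on signals above log2 2, it recovered 0% at a log2 size of 0.585, 12% at 1, 60% at 2 and 58% at 3. Of its 70 calls, 7.1% were false. These shares do not cover dimmer signals, nor the fit of 18075 probe sets, in which shared signals repeat. The simulation also took each signal's SD over these few arrays as its true spread, so recovery in the real data may differ. Alternatives were no level filter, higher levels, median centring, quantile normalization, centring on named small RNAs, a variance trend, array weights, a block for the rat number, an unmoderated test, other thresholds, 1 probe set per distinct signal and leaving out each array.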

Results

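Small RNAs were profiled in the kidneys of 3 rats made hyperoxaluric with ethylene glycol, which the body converts to oxalate, and ammonium chloride, which acidifies the urine. Kidneys of 3 age-matched rats on tap water served as controls. The study screened for microRNAs (miRNAs, short RNAs that repress messenger RNAs) that differed between the groups by more than 2-fold. Control probe sets aside, mature miRNA probe sets most often had values above log2 4. Their mean over the arrays lay above it in 16.1% of the 30424 mature probe sets, against 1.99% of the stem-loop probe sets, 1.07% of the Ensembl-numbered ones and 2.38% of those with a small RNA name. The share of all probe sets above log2 4 lay between 13.8% and 15.05% on each array. Over 1865 distinct signals above log2 4, arrays of hyperoxaluric rats correlated with each other at 0.961 to 0.979, arrays of control rats at 0.943 to 0.961, and arrays of different groups at 0.932 to 0.967, across genes.

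Nearly all miRNA signals that passed the test were higher in the hyperoxaluric kidneys. Of 18075 probe sets tested, 113 were higher and 7 lower at an adjusted p under 0.05 in limma, and all 120 were mature miRNA probe sets. They stand for 28 distinct higher signals and 2 distinct lower ones, so 93.3% of the changed signals were higher. The adjustment counts a shared signal once per probe set. With each distinct signal fitted once, 19 higher and 1 lower passed, all among these 30. The measured differences of the 28 higher signals ran from 1.42 to 3.97 on the log2 scale, with a median of 2.52, which is a median of 5.72-fold. Their mean levels ran from log2 2.31 to 9.4. In the control kidneys, 14 of the 28 already had a mean of log2 4 or more, 11 had a mean from log2 1 to under 4, and 3 were under log2 1. Of the higher signals, 7 had a mean over all arrays between log2 1 and 4, 16 between log2 4 and 8, and 5 above log2 8. Both lower signals lay between log2 1 and 4. Of all probe sets tested, 11.9% had no overlap between the groups, where chance gives 10% for 3 against 3. The 11.9% counts a shared signal once per probe set, and its distance from 10% was not tested.

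**Figure D1:**
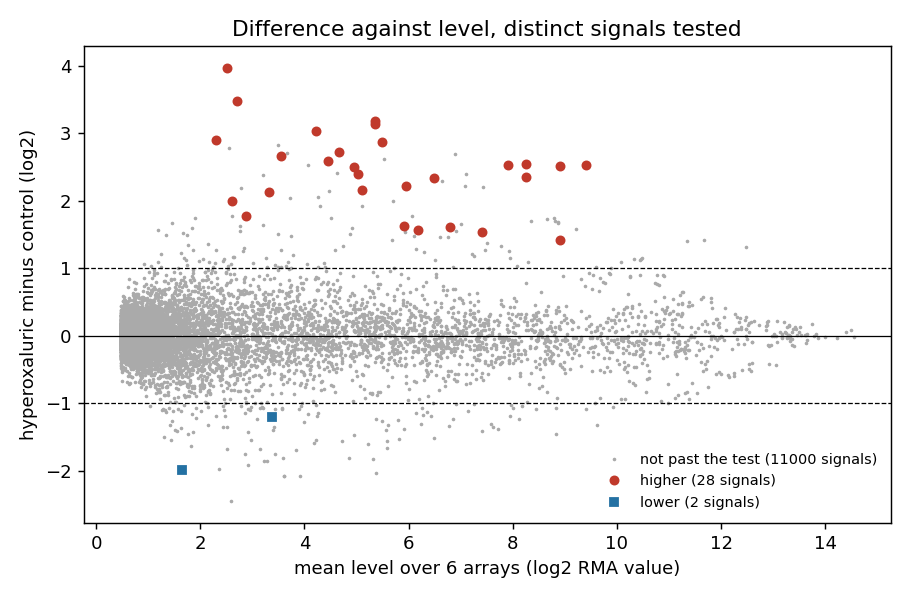
The difference between hyperoxaluric and control rats (log2, vertical axis) is plotted against the mean level over the 6 arrays (log2 RMA value, horizontal axis) for 11030 distinct signals; dashed lines mark 2-fold. The 28 higher signals (red circles) spread from log2 2.31 to 9.4, and the 2 lower ones (blue squares) lie below log2 4, while many grey signals beyond the dashed lines did not pass limma's test.

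Among the called signals, the largest measured difference was that of the mature miRNA probe set MIMAT0017158_st. It stood at 4.51 ± 0.46 (SD, n = 3) in hyperoxaluric and 0.54 ± 0.11 (SD, n = 3) in control kidneys. The difference was 3.97 with an SE of 0.25 (limma, adjusted p = 0.00655). The signal of MIMAT0006731_st, shared by 9 probe sets, rose from 0.96 ± 0.39 to 4.45 ± 0.62 (SD, n = 3 each), a difference of 3.49 with an SE of 0.36 (limma, adjusted p = 0.0151). Their control values lie close to 0.473, the median of all probe sets on these arrays, so the folds of 15.7 and 11.2, and the rank, set a signal against the array's background. The larger measured drop was that of MIMAT0001621_st, shared by 6 probe sets. It fell from 2.65 ± 0.22 in control to 0.66 ± 0.21 in hyperoxaluric kidneys (SD, n = 3 each), a difference of -1.98 with an SE of 0.19 (limma, adjusted p = 0.0103). Its hyperoxaluric values lie close to the same background, so this difference too sets a signal against background. MIMAT0017312_st stood at 3.97 ± 0.24 in control and 2.77 ± 0.04 in hyperoxaluric kidneys (SD, n = 3 each), a 2.3-fold difference near the threshold (limma, adjusted p = 0.0467), and it did not pass in any of 10 alternatives, where its adjusted p ran from 0.0683 to 0.337. These 10 alternatives were median centring, quantile normalization, the block for the rat number, a variance trend and the fits without each array. The other alternatives were not tallied for single accessions. Of the same 10, MIMAT0017158_st passed in 8, MIMAT0006731_st in 5 and MIMAT0001621_st in 6, with highest limma adjusted p of 0.109, 0.145 and 0.128.

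The number of calls depended on single arrays, although every fit without an array also leaves fewer degrees of freedom. Without hyperoxaluric rat 3, limma called 0 probe sets (smallest adjusted p 0.0568), with 1179 at an unadjusted p under 0.05 against 1254 with all arrays. Without hyperoxaluric rat 1 it called 12, without hyperoxaluric rat 2 it called 67, without control rat 1 it called 62, without control rat 2 it called 66 and without control rat 3 it called 119 higher and 7 lower. The unmoderated test called 0 probe sets with all arrays, with 1221 at an unadjusted p under 0.05. These counts take a shared signal once per probe set, and 1254 is 6.94% of the probe sets tested. Fitted once each with limma on all arrays, 506 of 11030 distinct signals were under 0.05, no larger a share than chance gives.

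The fold screen gave far more signals than the test. Beyond 2-fold lay 427 higher and 352 lower probe sets, or 147 and 116 distinct signals. Of these 263 distinct signals, 30 (11.4%) passed limma's test, and 167 (63.5%) had no overlap between the groups. Signals picked for a large difference of means tend not to overlap, so the 63.5% is no separate result. It was not counted in other splits of the arrays. None of the 120 called probe sets lay under 2-fold. Of the distinct signals beyond 2-fold with a mean above log2 4, 21 passed (15.9%), and of those below it, 9 of 131 (6.87%). The 9 other splits of the same arrays into 3 and 3 gave 166 to 273 distinct signals beyond 2-fold, or 385 to 678 probe sets against 779. The number of lower probe sets depended on single control arrays: it was 651 without control rat 1, 877 without control rat 2 and 227 without control rat 3.

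Stem-loop probe sets, which target miRNA precursors, showed no change that passed the test. Among 1892 tested, 2 lay beyond 2-fold higher and 1 beyond 2-fold lower. Fitted apart with limma, 0 passed, 91 had an unadjusted p under 0.05, and the smallest adjusted p was 0.34. Few stem-loops gave a signal: above log2 2 there were 190 distinct stem-loop signals and 2834 distinct mature ones. At that level 0 of the stem-loop signals and 29 of the mature ones had passed, a difference that itself did not pass (two-sided Fisher's exact test across signals, p = 0.256).

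Probe sets named after small nucleolar RNAs, which guide chemical modification of other RNAs, also showed no change that passed. Only 12 of the 505 probe sets with a small RNA name had a mean above log2 4. Whether these probe sets match rat RNAs was not checked. None of the tested probe sets with a small RNA name passed limma's test, 0 had an unadjusted p under 0.05 in the joint fit and 4 in a fit of their own. In the joint fit the smallest adjusted p was 0.744. The 516 Ensembl-numbered probe sets gave 0 calls, with 7 at an unadjusted p under 0.05 in the joint fit and 20 in their own. The brightest named RNA, snR39B, stood at 7.71 ± 0.19 in hyperoxaluric and 7.75 ± 0.27 in control kidneys (SD, n = 3 each). U46 stood at 6.9 ± 0.3 and 7.0 ± 0.14, and HBII-429 at 6.78 ± 0.15 and 7.01 ± 0.19 (SD, n = 3 each). The H/ACA-type RNA ACA57 stood at 5.77 ± 0.35 and 5.86 ± 0.16 (SD, n = 3 each). Only HBII-85-26, of a snoRNA family from an imprinted locus, lay beyond 2-fold, at 4.91 ± 1.26 and 3.83 ± 1.36 (SD, n = 3 each), and its difference of 1.08 had an SE of 0.88 (limma, adjusted p = 0.934). Single arrays moved it: it was 0.35 without hyperoxaluric rat 1, 1.85 without control rat 1, 0.559 without control rat 2 and 0.828 without control rat 3. A second probe set of HBII-85-26 gave a difference of 0.52. Among 18 RNAs with 2 probe sets above log2 1, the paired differences had the same sign in 12 and lay a median of 0.137 apart.

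**Figure D2:**
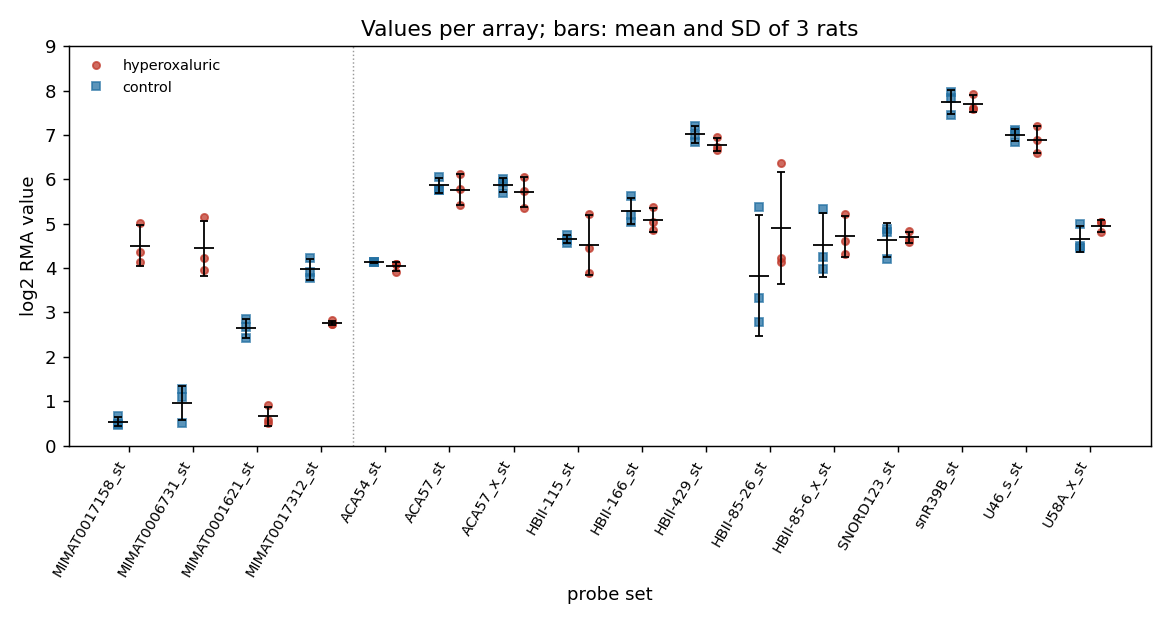
Log2 RMA values (vertical axis) of each array are shown for 4 mature miRNA accessions left of the dotted line and for the named small RNAs with a mean above log2 4 right of it, with hyperoxaluric rats as red circles, control rats as blue squares, and bars for the mean and SD of 3 rats. The groups separate fully for the 4 accessions, as the rule that picked them required, and also for ACA54, at a difference of only -0.09. The widest spread among the named RNAs is that of HBII-85-26, with an SD of 1.26 and 1.36.

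As whole groups, no type or family of probe sets shifted past the test (camera, 6 groups, smallest adjusted p = 0.114, and 0.684 with an estimated correlation). That smallest value belonged to the Ensembl-numbered signals, of which 23 of 74 were higher, with a median difference of -0.10. Of the mature miRNA signals above log2 1, 2214 of 4403 were higher, with a median difference of 0.00352, and 30 passed the test singly. Of the H/ACA-named signals, 2 of 11 were higher, with a median difference of -0.03 (adjusted p = 0.315). Of the HBII-85 family signals, 4 of 5 were higher, with a median difference of 0.32 (adjusted p = 0.252). Stem-loop signals had 198 of 480 higher (median -0.04, adjusted p = 0.301), and the other named RNAs 14 of 32 (median -0.05, adjusted p = 0.315). Without hyperoxaluric rat 2, 3 groups passed: the Ensembl-numbered and H/ACA-named signals as lower and the mature signals as higher, each at an adjusted p of 0.0355. The Ensembl-numbered signals also passed without hyperoxaluric rat 3 (adjusted p = 0.00531), and the HBII-85 family without control rat 1 (adjusted p = 0.0136). Without hyperoxaluric rat 1, 0 groups passed (camera, adjusted p = 0.846 for each). There the H/ACA-named and stem-loop signals turned higher and the mature ones lower. Without control rat 2 or control rat 3, 0 groups passed. Since camera sets each group against all other signals, most of them mature, opposite shifts of mature and other signals are not separate results.

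Control probe sets varied between the arrays within a group. The bioB hybridization controls stood at 9.34 on the array of hyperoxaluric rat 1 and at 9.6 to 9.99 on the others, with group means of 9.69 ± 0.33 and 9.78 ± 0.16 (SD, n = 3 each) for hyperoxaluric and control rats. Spike-in control 36 ran from 12.7 on the array of hyperoxaluric rat 2 to 14.02 on that of hyperoxaluric rat 1, with group means of 13.3 ± 0.67 and 13.4 ± 0.18 (SD, n = 3 each). The first principal component of the signals above log2 4 held 36.3% of the variance and placed hyperoxaluric rat 1 at 21.8, the other hyperoxaluric rats at 7.93 and 3.19, and the control rats at -2.72, -13.9 and -16.3.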

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

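The comparison of control probe sets was chosen after the data were seen. On 2 of the 43 control probe sets above log2 2, every hyperoxaluric array lay above every control array, and on 2 every one lay below. Chance gives 5% each way, or 2.15 probe sets. The 2 that lay above were a bioD hybridization control (AFFX-r2-Ec-c3-bioD-5_at), by 0.165 on the log2 scale, and spike-in control 2, by 0.00583.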

How the results depend on the processing

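The alternatives that raise the level filter, take 1 probe set per distinct signal or fit mature probe sets apart were chosen after seeing the data. So were those for type shifts, and the others were set before the data were examined. Centring on the named small RNAs was listed with the others, but the RNAs it uses were chosen after their values were seen. The 113 higher probe sets (28 distinct signals) stayed within 1.5 times under every alternative except the replicate block, the unmoderated test and the fits without single arrays. Quantile normalization gave the fewest of the rest on the same probe sets, 87, of which 19 of the 28 signals were among the calls. With 1 probe set per distinct signal, 19 signals were called higher, all among the 28. With the rat number as a replicate block, 0 probe sets were called higher and 0 lower (smallest adjusted p 0.109; 1129 at an unadjusted p under 0.05). The block takes 2 of the 4 residual degrees of freedom, and no array correlated best with its own number. The unmoderated test also called 0 higher and 0 lower (smallest adjusted p 0.0926). The few lower calls moved more: 7 probe sets became 14 with trend and robust variance, 12 at an adjusted p of 0.1, 3 above log2 2 and 2 above log2 4, and 2 distinct signals became 4 with trend and robust variance, 4 after centring on the named small RNAs, 6 at an adjusted p of 0.1, 1 above log2 1 and 1 with 1 probe set per signal. Leaving out 1 array gave 0 to 119 higher and 0 to 7 lower probe sets, or 0 to 27 and 0 to 2 distinct signals. It gave 440 to 605 higher and 227 to 877 lower probe sets beyond 2-fold, 0 changed stem-loop probe sets in each case, and 0 to 3 shifted types. At 1.5-fold the screen gave 1117 higher and 1093 lower probe sets, and above log2 4 it gave 148 lower ones at 2-fold. For the stem-loops and type shifts, the replicate block changed no call. The causes were not tested, except that fewer arrays or a block leave fewer degrees of freedom. The planned detection filters from plant probe sets and the alternatives for miRNA lists, arms, rat stem-loops and orthologous probe sets were not run, since no table named the probe sets. No detection calls were used, so signals near log2 0.473 were not told apart from background.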

Other observations

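In the second paragraph, the tests of repeated counting and of centring on named RNAs were chosen after their results were seen, and that of the smallest p after the calls without single arrays were seen; the count of splits by distinct signals in the third was also chosen afterwards. The other tests were written before their results. The changed miRNA signals tended to be those that many probe sets share. Among 2834 distinct mature signals above log2 2, 752 were shared by at least 2 probe sets and 2082 were single. Of the shared signals 2.53% were called (19), and of the single ones 0.48% (10). Shared signals were also brighter, with a median level of log2 6.55 against 4.54. Within bins of level, 7.09 calls on shared signals were expected, and calls were 5.87 times as frequent, relative to expectation, on shared as on single signals (one-sided permutation test, 10000 resamples, p = 1e-04, the smallest they can give). In the fit with 1 probe set per signal, 14 of the 19 calls above log2 2 were on shared signals. A hypothesis is that shared signals belong to miRNA sequences conserved between organisms, which may include most of the miRNAs a rat kidney expresses, while single signals may include probe sets of other organisms that hybridize in part. No species names were used to test it, and signals of near-identical sequence are not independent, so the p-value is too small to an unknown degree.

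The calls lean to the higher side, 28 distinct signals against 2. Centring every array on the named small RNAs, 12 probe sets above log2 4, took 0.0493 off every difference. Their own differences ran from -0.23 (HBII-429) to 1.08 (HBII-85-26, SE 0.88). Most were lower in the hyperoxaluric kidneys, so the sign of the 0.0493 rests on HBII-85-26, which single arrays moved. RMA had already fixed the overall level of every array. The centring therefore could not decide whether whole arrays had shifted, and no conclusion is drawn from it. The centring moved single arrays by -0.231 to 0.292. By that subtraction the median difference of the called higher signals became 2.47, against 2.52. After it, 27 distinct signals were called higher and 4 lower. The test written beforehand, the median difference of the 1769 distinct mature signals above log2 4 (0.00533), is not used, since RMA makes the arrays' distributions alike and mature probe sets make up most of that level. A shift confined to some levels, or to mature miRNA probe sets, was not tested. Whether 1 treated array alone gave the lean was asked of signals picked without that array. Of the 30 distinct signals with the smallest p in the limma fit without hyperoxaluric rat 1, 27 were higher, and 29 without hyperoxaluric rat 2 and 27 without hyperoxaluric rat 3. So the signals with the smallest p leaned higher without each treated array in turn. The counts decide no more than that: the fits share control arrays, the lean in other splits was not counted, and related sequences could not be grouped. Fewer signals were called in these fits: 4 distinct ones higher and 0 lower without hyperoxaluric rat 1, 12 and 1 without hyperoxaluric rat 2, and 0 and 0 without hyperoxaluric rat 3. The differences of the 28 higher signals came to between 0.866 and 1.14 times their full size in the same fits, although signals called for a small spread are bound to move little. Likewise the test written beforehand, whether the other 2 treated arrays stayed above every control array without hyperoxaluric rat 2 (28 of 28), was fixed by the lack of overlap in called signals and is not used. Repeated counting of few related RNAs stays open: with each distinct signal fitted once 95% of the calls were higher, but all 20 of these were among the 30 called signals, and related sequences cannot be grouped without names. The real split called 120 probe sets and the highest other split of the 6 arrays called 0; only 1 of the 10 splits reached the real count, and 10 splits are too few for a share under 0.05. The treatment, the choice of rats by urinary oxalate and any shared handling of a group stay open and were not tested.

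Most signals beyond 2-fold did not pass the test. The share that passed was 2.32 times as high above log2 4 as below it, between the bounds set beforehand (at least 3 if the spread of dim signals was the cause, under 1.5 if not), so that explanation stays open. The real split gave 779 probe sets beyond 2-fold and the highest other split gave 678; only 1 of the 10 splits reached the real count, and 10 splits are too few for a share under 0.05. Counted as distinct signals, the real split gave 263 and the highest other split 273.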
